A study of Drosophila melanogaster with 2 samples.

How the data were processed

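The series holds chromatin immunoprecipitation sequencing (ChIP-seq) of whole Drosophila melanogaster embryos aged 0 to 24 h that carried a transgene encoding the protein product of CG10321 fused to enhanced green fluorescent protein (eGFP). Per the labels, the fusion protein was precipitated with an antibody against GFP, chromatin was fragmented by sonication to 200 to 800 bp, and 2 biological replicates were made. Both samples belong to 1 group. The labels name a possible control experiment, which was not analysed here, and no comparison between treatments or stages was possible.

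The deposited files were peak lists in dm6 coordinates. Each replicate had a ranked list and a thresholded list, and the series had 2 thresholded lists and 2 ranked lists that drew on both replicates, per the deposited file lists. Per the deposited file lists, each list was derived from the replicates' alignments and a further file that both replicates share, and a signal track derived from the same files is described there as a fold change over control. What that control was, the aligner, the peak caller and their versions are not given in the sources used here. Column 5 of the deposited lists held a score in whole numbers up to 1000, read here as a scaled irreproducible discovery rate because the file lists name that measure, and no thresholded peak scored below 830. Column 7 held the signal value that the authors' peak caller gave each peak, on a scale not given in the sources used here. Column 10 of the deposited lists gave the distance from the peak start to its summit. The signal values were the authors' own and were used to describe, rank and filter peaks within a list. Between the replicate lists only the ranks of the values of shared peaks were compared. Further columns of the series' ranked lists, 16 in all, held values of single inputs with no name to match to a replicate, and were not used. The lists held no read counts, so the depth of each sample is unknown, and all intervals cover counting error over peaks or genes only.

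The thresholded lists held 2003 peaks for replicate 1, 2133 for replicate 2, 3012 in the conservative list of both replicates and 3468 in the other list of both replicates. Every peak of a thresholded list was found in a ranked list among the peaks that scored at least 830, and this nesting was used to tell which ranked list belonged to which thresholded list. The conservative list was the main list. Its 6 peaks on unplaced sequences were left out, which left 3006 peaks on the arms 2L, 2R, 3L, 3R, 4, X and Y.

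Gene models came from the Ensembl annotation release 115 and sequence from the RefSeq copy of the same assembly, whose arm lengths no peak exceeded. Annotated transposable element insertions were not counted as genes, which left 18277 genes, 13968 of them protein-coding. A transcription start site (TSS) was the 5' end of any annotated transcript. A gene was called bound when a summit lay within 500 bp of a TSS. Gene symbols were matched exactly or through a synonym that pointed to a unique gene, and 4 symbols found no match.

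Replicate lists were compared by peaks that shared at least 1 bp, against 1000 random relocations of a list within its arms over bases other than N, with a one-sided permutation p whose smallest possible value was 0.001. The share of summits near a TSS was tested against the same kind of relocation, one-sided. Genomic classes (promoter, 5' UTR, 3' UTR, coding, other exon, intron, intergenic, in this order of precedence) were tested two-sided. Arms were compared with their length by exact binomial tests. The 19 gene lists were compared with all other protein-coding genes by two-sided Fisher's exact tests, and odds ratios were given with 95% intervals after adding 0.5 to each cell. The 20 consensus sequences were searched on both strands within 50 bp of each summit and in 2 windows centred 500 bp to each side, with two-sided Fisher's exact tests. Words of 8 bp present in at least 5 windows were compared with the same flanks by one-sided Fisher's exact tests. P-values of each family were adjusted by the Benjamini-Hochberg method and called at 0.05. Intervals of shares are Wilson 95% intervals. Shares were also computed from each replicate's own thresholded list and given as a mean with the SD over n = 2. Genes and peaks are not biological replicates, so these tests describe the lists and not the spread between embryos.

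The lists, the consensus sequences and the rule for named genes were fixed before the data were examined. The lists of cell types were read as gene groups, since whole embryos hold all of these cells. Named were the 25 peaks of highest signal in the conservative list that a peak of both replicates overlapped, with the gene of the nearest TSS, the up to 4 bound members of each list with the highest signal, CG10321 itself, and the 10 consensus sequences and 10 words with the smallest p. An item that this rule names among the strongest peaks is not reported here. The alternatives were the other thresholded list, each replicate's list alone, the upper part of the list by signal, TSS distances of 200 and 1000 bp, other backgrounds, windows of 100 bp to each side, words of 6 bp, and other definitions of a shared peak. The counts of summits upstream and downstream of the TSS and of RNA genes by biotype were chosen after the data had been seen. The same holds for the settings with overlapping peaks reduced to the strongest, peaks near CG10321 left out, passing ranked peaks added back, mtd left out of the insulator list or divergent promoters counted by the nearest gene only, and for 3 further gene lists.

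The procedures were tested on simulated lists. A planted TSS-proximal share of 48.1% was recovered as 48.6% over 3006 simulated peaks, and a planted overlap of 60% as 60.7%. Random lists gave on average 0.1 of 7 arms, 0.15 of 20 consensus sequences and no 8 bp word called. Random sets of bound genes gave on average 0.4 of 19 gene lists called, so the gene list test is somewhat liberal. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.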

Results

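Binding of a CG10321-eGFP fusion protein was mapped by ChIP-seq in whole Drosophila embryos aged 0 to 24 h, in 2 biological replicates of 1 group. The data analysed were lists of peak positions in dm6, with the signal value that the authors' peak caller gave each peak. Read depth is unknown. No control library was analysed here, so the values below describe the peaks the authors called and were not set against a background measured in the same way. A gene was called bound when a peak summit lay within 500 bp of 1 of its transcription start sites (TSSs).

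The replicates were compared first, to see how far their peaks coincided. Of the 1996 peaks of replicate 1 on the main arms, 1369 overlapped a peak of replicate 2, a share of 68.6% (Wilson 95% interval 66.5 to 70.6). Of the 2128 peaks of replicate 2, 1397 overlapped a peak of replicate 1, a share of 65.6% (63.6 to 67.6). Relocated peaks overlapped at 0.912% and 0.859%, and both permutation p-values were 0.001, the smallest that 1000 relocations can give. Against the ranked list of the other replicate, 96.5% of replicate 1 peaks and 98.4% of replicate 2 peaks overlapped a peak of any score. Relocated peaks did so at 35.3% and 32.9%, over 100 relocations. Of the 3006 peaks of the conservative list, 1377 (45.8%) overlapped a peak of each thresholded replicate list and 770 overlapped a peak of neither. Peaks found in both thresholded replicate lists were the stronger ones. In replicate 1 the median signal was 99.9 for shared peaks and 48.6 for the 627 others, and in replicate 2 it was 103 for shared peaks and 51.1 for the 731 others. Across the 1369 shared peaks Spearman's rho of the signal values was 0.827 (95% interval 0.809 to 0.844), a value across peaks, which are not independent replicates. The summits of shared peaks lay a median of 15 bp apart.

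**Figure D1:**
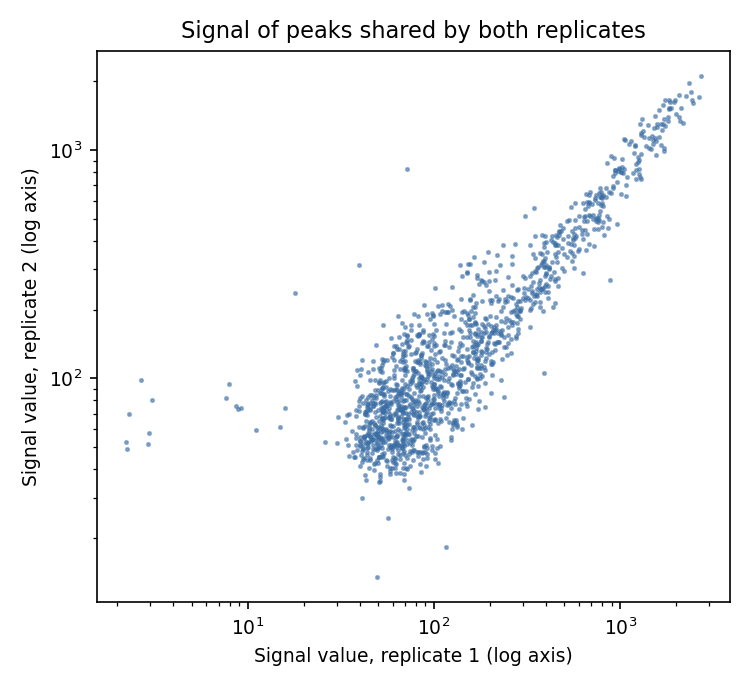
Signal value (the authors' scale, log axes) of each peak shared by both replicates, replicate 1 on the x axis and replicate 2 on the y axis, with 1 point for each of 1369 peaks. Spearman's rho was 0.827.

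Of the 25 strongest peaks shared by both replicates, 5 had a gene of the Hox and embryonic patterning list as the nearest protein-coding gene, and 11 had a gene of that list or of the homeobox, T-box, Sox, Pax and forkhead lists written after these peaks had been seen. The highest signal of all, 4854, was 90 bp upstream of Ip6k, an inositol hexakisphosphate kinase gene, at 2R 21645791 to 21646348. This was also the strongest peak in both replicates (2710 and 2117). It lies within 10 kb of CG10321, the gene of the tagged protein, and signal from transgene copies there cannot be told apart from binding. Homeobox genes among the 25 with summits in the promoter included otp (signal 4188, 251 bp upstream of the TSS), toy of the Pax family (3620, 121 bp upstream), ap (3552, 146 bp upstream), eyg (3424, 168 bp upstream), oc (3401, 286 bp upstream), ems (3335, 164 bp upstream) and cad (3325, 167 bp upstream). The GATA factor gene grn (3451), the Sox gene Sox21b (3396) and the pair-rule gene opa (3298) also carried promoter summits.

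In the bithorax complex, the peak ranked second (signal 4326, 3R 16869269 to 16869719) lay in an intron of MSAmiP and of the noncoding RNA gene iab8, 13176 bp upstream of mir-iab-8. Another (3782, 3R 16847207 to 16847613) also lay in an intron of MSAmiP and of iab8, 1271 bp downstream of a start site of the noncoding RNA iab8. Summits also lay in the 3' UTR of tio (4297), in the 5' UTR of Uba1, the gene of the ubiquitin-activating enzyme (3990), and in introns of mts (3494), ssp3 (3446), mod(mdg4) (3171) and the tracheal regulator gene trh (3135). The peaks at dikar (4104), CG11151 (3667), scny (3450) and nsl1 (3157) were promoter peaks, and the peak nearest to the noncoding RNA gene CR45297 (4066) was intergenic. Of the 25 strongest peaks shared by both replicates, 16 lay within 500 bp of a TSS, and all 25 were also overlapped by the other thresholded list.

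Peaks were concentrated just upstream of start sites. Of 3006 summits, 1418 lay within 500 bp of a TSS, a share of 47.2% (45.4 to 49.0), against 13.6% of relocated summits (permutation p = 0.001, one-sided, the smallest that the relocations can give). The share was 50.7% in the replicate 1 list and 49.3% in the replicate 2 list (SD 0.926, n = 2). Of the TSS-proximal summits that did not fall on the TSS itself, 1016 were upstream and 397 downstream, so 71.9% were upstream (69.5 to 74.2), and 74.9% ± 2.79 (SD, n = 2) in the replicate lists. The bins from 200 to 101 bp and from 100 to 1 bp upstream held 399 and 339 summits.

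**Figure D2:**
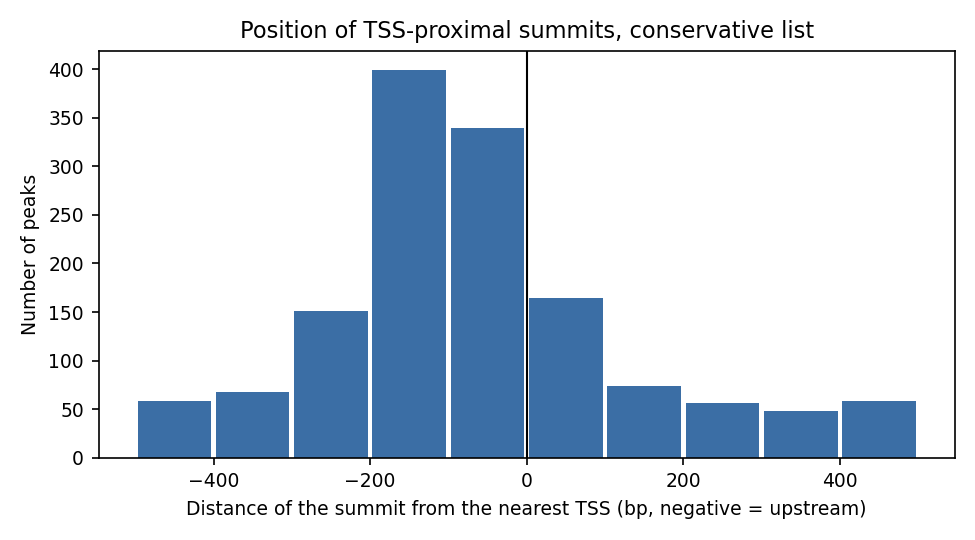
Number of conservative-list peaks (y axis) by distance of the summit from the nearest TSS in bins of 100 bp (x axis, negative values upstream). The fullest bin, with 399 peaks, lies 200 to 101 bp upstream of the TSS.

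Of all summits, those in promoters included, introns held 34.3%, below the 39.5% of relocated summits, and intergenic sequence held 13.5% against 27.2%. Coding sequence held 1.30% against 13.1%, and 3' UTRs 1.33% against 5.12%. Each of these 4 classes differed from relocation with an adjusted permutation p of 0.0028. Promoters held 47.2% of all summits against 13.6%, which leaves smaller shares for the other classes. Whether a class was more or less frequent among the summits outside promoters alone was not tested. Of the 4 classes, introns were reduced least (ratio 0.869), followed by intergenic sequence (0.499) and 3' UTRs (0.260). The ratio for coding sequence was 0.0991, and it ran from 0.0253 among the stronger peaks to 0.177 in the other thresholded list, with 0.0648 and 0.0358 in the lists of replicates 1 and 2. The 5' UTR (1.13% against 0.782%, adjusted permutation p = 0.046) and other exons (1.20% against 0.807%, adjusted permutation p = 0.030) lay slightly above it. The 5' UTR call was lost in the other thresholded list (ratio 1.29, adjusted permutation p = 0.18) and in the replicate 2 list alone (ratio 1.19, p = 0.50). Among the stronger peaks, which are fewer, neither class passed, with ratios of 1.43 for the 5' UTR (adjusted permutation p = 0.20) and 1.63 for other exons (p = 0.086), against 1.45 and 1.48 in the full list.

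Among arms, X held 600 of 3006 peaks (95% interval 18.6% to 21.4%) against 17.1% of the sequence length (exact binomial test, adjusted p = 0.00018), and 21.4% ± 0.455 (SD, n = 2) in the replicate lists. Arm 4 held 15 peaks, 0.499% against 0.971% (exact binomial test, adjusted p = 0.016). Y held 0 of 3006 peaks against an expected 2.49% (exact adjusted p = 1.4e-32). The expected shares count every base other than N, and whether reads could be placed uniquely on Y was not examined. The arms 2L (18.1% against 17.2%), 2R (19.0% against 18.4%), 3L (20.7% against 20.4%) and 3R (21.7% against 23.4%) did not pass the test. The arm 4 call was lost in the replicate 1 list alone (exact adjusted p = 0.53), among the stronger peaks (0.36) and when the expected share followed the number of genes (0.36). By gene number 2L lay below its share (ratio 0.918, exact adjusted p = 0.043) and 3R passed, also below its share (ratio 0.917, exact adjusted p = 0.025). In the replicate 2 list alone 2L lay above its share by length (ratio 1.13, exact adjusted p = 0.013), and in the other thresholded list 3R lay below it (ratio 0.918, exact adjusted p = 0.013). A further 124 ranked peaks on these arms scored at least 830 but were absent from the conservative list, 68 of them on 3R and 39 on 2L. Arm shares with these peaks added back were not computed, so the low share of 3R holds only without them.

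Genes that pattern the embryo were bound most often of the 19 lists. Of 13968 protein-coding genes 1525 were bound, 10.9%. Of the 39 Hox and embryonic patterning genes 23 were bound, 59.0%, with an odds ratio of 11.9 (95% interval 6.26 to 22.2, Fisher's exact test, adjusted p = 4.1e-12) and 60.3% ± 1.81 (SD, n = 2) in the replicate lists. The odds ratio was 19.0 in the replicate 1 list alone, 16.5 in the replicate 2 list alone and 20.1 among the stronger peaks. The strongest were oc, ems, cad and opa, with signals of 3401, 3335, 3325 and 3298. Of 20 genes of insulator and architectural proteins 10 were bound (odds ratio 8.21, 3.48 to 19.3, exact adjusted p = 4.9e-05), and 37.5% ± 3.54 (SD, n = 2) in the replicate lists, led by pzg (2575), Clamp (1060), Trl, which encodes GAGA factor (622), and Chro (444). The member mod(mdg4) was not counted as bound, since its strong peak (3171) had its summit 996 bp from the nearest TSS. Without mtd, a member not known as an insulator protein that was left out after the values had been seen, 9 of 19 were bound (odds ratio 7.38, 3.08 to 17.9, exact adjusted p = 0.00023). Of 20 heat shock protein genes 6 were bound (odds ratio 3.51, 1.45 to 9.26, exact adjusted p = 0.040), led by Hsp68 (1515), Hsc70-4 (1467), Hsp27 (205) and Hsp83 (182). The heat shock call was lost in the other thresholded list (exact adjusted p = 0.062) and with a TSS distance of 1000 bp (exact adjusted p = 0.088).

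Genes of cytoplasmic ribosomal proteins were also bound often, with lower signals. Of 93 genes 44 were bound (odds ratio 7.51, 4.999 to 11.3, Fisher's exact test, adjusted p = 1.7e-17), and the highest signals were 288 at RpL7, 255 at RpS27, 190 at RpL14 and 161 at RpL23A. The median signal at the bound ribosomal protein genes was 106, against 925 at the bound patterning genes and 112 at all bound genes. The replicates differed in this group: 50.5% of the genes were bound in the replicate 1 list (odds ratio 12.4) and 20.4% in the replicate 2 list (odds ratio 2.92, exact adjusted p = 0.00049). Of 51 translation factor genes 13 were bound (odds ratio 2.81, 1.54 to 5.36, exact adjusted p = 0.0072), led by eIF6 (524), eIF4EHP (332), eIF4G2 (231) and eEF1gamma (180). The translation factor call was lost in the replicate 2 list alone (exact adjusted p = 0.33) and with a TSS distance of 200 bp (exact adjusted p = 0.11).

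Gene families with no bound member were the 179 chemosensory receptors (Fisher's exact test, adjusted p = 9.8e-09), the 108 cuticle proteins (exact adjusted p = 2.5e-05) and the 111 replication-dependent histones (exact adjusted p = 2.0e-05). The histone genes are near-identical repeats in a cluster at 2L 21416953 to 21541681, so they are not independent. Whether reads could be placed uniquely there was not examined, and 4 peaks of any rank had a summit in the cluster. The peak 72 bp upstream of His3:CG31613 (signal 246) scored at least 830 but was absent from the conservative list. With such peaks added back, a setting chosen after the data had been seen, the odds ratio was 0.144 (exact adjusted p = 0.0012). With a TSS distance of 1000 bp the odds ratio of the chemosensory receptors was 0.109 (exact adjusted p = 3.1e-07). The histone call was lost against genes with a ranked peak (exact adjusted p = 1).

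The remaining lists did not pass the test. Of 23 Polycomb and trithorax group genes 6 were bound (odds ratio 2.89, 1.23 to 7.49, Fisher's exact test, adjusted p = 0.070), with signals of 2784 at Su(z)2, 2270 at ph-p, 2092 at ph-d and 1172 at Asx. This list passed the test in each replicate's list alone (exact adjusted p = 0.018 for replicate 1 and 0.0049 for replicate 2), in the other thresholded list (0.042), among the stronger peaks (0.0054) and with only the nearest gene counted (0.022). Of 24 neural genes 6 were bound (exact adjusted p = 0.076), led by the glial regulator gene repo (619), elav (243), Gad1 (110) and mira (92.4). Bound members of the list of midgut, fat body, blood and trachea genes were vvl (1695), fkh (329), trh (240) and grh (122), 4 of 18 (exact adjusted p = 0.22), and among the stronger peaks this list passed (exact adjusted p = 0.042). The stronger intron peak of trh (3135) had its summit 836 bp from the nearest TSS and was not counted here. Of 23 muscle genes wupA (143), sls (131), up (109) and mbc (54.7) were bound (exact adjusted p = 0.42), and of 13 germ line genes zpg (1059) and bgcn (127) were bound (exact adjusted p = 0.72).

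The other housekeeping lists did not pass either. Of 73 mitochondrial ribosomal protein genes 10 were bound (exact adjusted p = 0.53), led by mRpL53 (2628), mRpL41 (716), mRpS10 (551) and mRpS23 (544). Of 80 genes of the respiratory chain and ATP synthase 7 were bound (exact adjusted p = 0.76), led by ND-39 (224), ND-ASHI (120), ND-24 (91.0) and COX6B (86.6). The bound spliceosome genes were snRNP-U1-70K (646), Prp3 (92.4), SmD3 (79.1) and B52 (77.9), 4 of 21 (exact adjusted p = 0.41). The bound cell cycle and replication genes were dup (624), CycE (113), dpa (83.7) and stg (77.5), 4 of 33 (exact adjusted p = 0.78). Rpn3 (109) and Rpt3 (78.2) were the bound members of 48 proteasome genes (exact adjusted p = 0.26), and E(spl)mbeta-HLH (120) and E(spl)m3-HLH (99.9) those of the 11 genes of the Enhancer of split complex (exact adjusted p = 0.43).

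**Figure D3:**
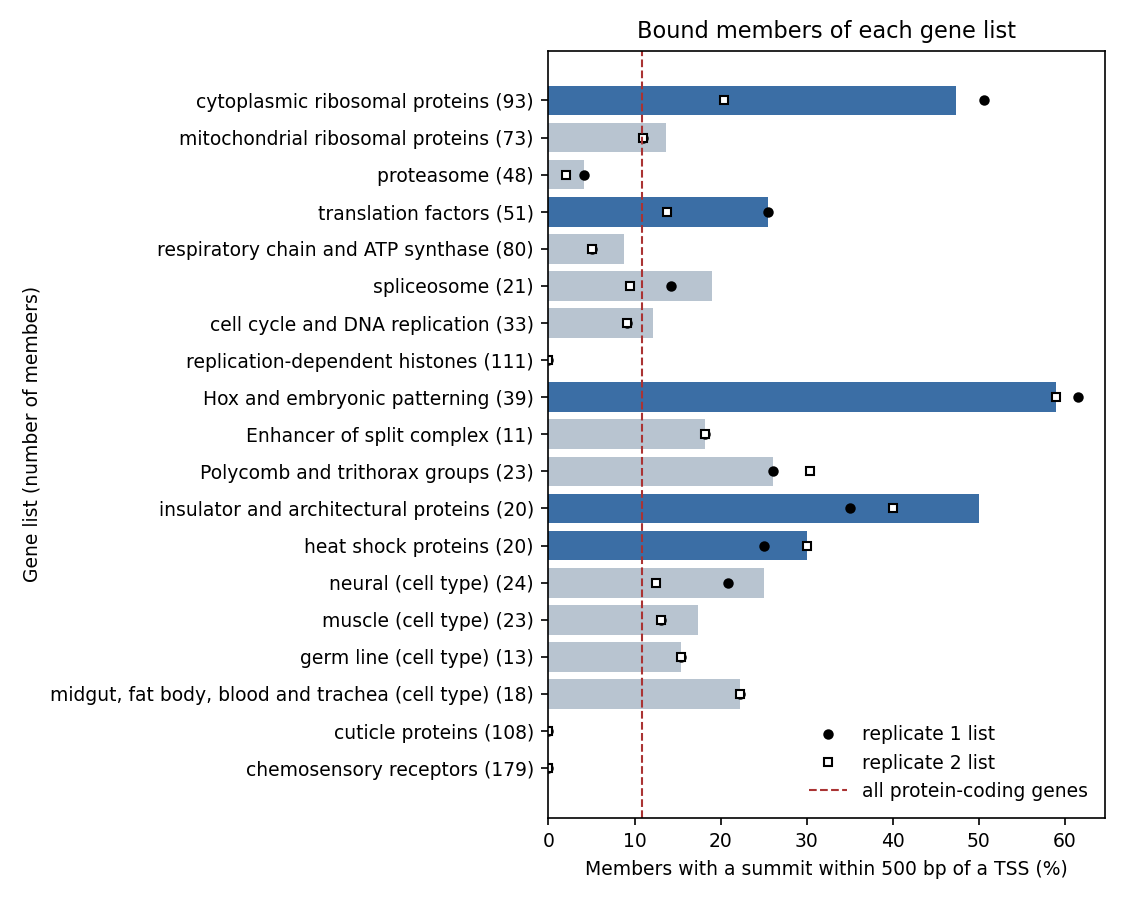
Percent of the members of each gene list with a summit within 500 bp of a TSS (x axis) for the 19 lists (y axis, number of members in brackets). Bars show the conservative list, dark where the adjusted p was below 0.05 and pale where it was not, points and squares the lists of replicates 1 and 2, and the dashed line all protein-coding genes (10.9%), and the 3 lists without a bar had 0 bound members and passed the test.

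GA-rich sequence marked the summits. The GAGA element GAGAGAG, the site of GAGA factor, was found within 50 bp of 11.6% of summits and in 2.46% of flanking windows (odds ratio 5.19, Fisher's exact test, adjusted p = 3.5e-65), and in 13.0% ± 3.26 (SD, n = 2) of summits in the replicate lists. The pyrimidine-rich initiator YYCTTTYY was found at 19.4% against 12.5% (exact adjusted p = 2.0e-16). It was matched on either strand, so matches to its reverse complement RRAAAGRR (R for a purine) can lie in GA-rich sequence. Ohler motif 7 was found at 5.32% against 3.26% (exact adjusted p = 2.7e-05), the CTCF core at 2.23% against 1.08% (exact adjusted p = 0.00014) and Ohler motif 5 at 5.99% against 4.66% (exact adjusted p = 0.027). The homeodomain core TAATTR was rarer at summits, 11.8% against 15.3% (exact adjusted p = 3.1e-05), as was the initiator TCAGTY, 7.78% against 9.33% (exact adjusted p = 0.042). G and C made up 43.2% of the bases of summit windows and 41.4% of those of flanks, on average. No motif test was adjusted for this difference, which bears most on the calls with ratios near 1.

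The BEAF-32 core (13.8% against 12.4%, exact adjusted p = 0.12), Ohler motif 1 (0.466% against 0.233%, exact adjusted p = 0.15) and the DRE (0.898% against 0.549%, exact adjusted p = 0.15) did not pass in the conservative list. In the replicate 1 list alone the BEAF-32 core (exact adjusted p = 1.8e-05) and the DRE (exact adjusted p = 0.00025) passed, and in the other thresholded list the DRE (0.0056) and Ohler motif 1 (0.022) passed, as did the DRE in wider windows (7.1e-05). Against windows at the same distance from the TSS of unbound genes, none of these 3 passed, and their ratios were 0.799 for the DRE (exact adjusted p = 0.83), 0.884 for the BEAF-32 core (0.30) and 0.758 for Ohler motif 1 (0.86). Against the same control GAGA (9.16% against 1.91%, exact adjusted p = 8.4e-23) and YYCTTTYY (16.7% against 9.24%, exact adjusted p = 2.5e-10) passed, as did Ohler motif 7 (ratio 1.42, exact adjusted p = 0.029), the homeodomain core (ratio 0.798, 0.029) and the initiator TCAGTY (ratio 0.734, 0.024). The CTCF core (ratio 1.78, exact adjusted p = 0.11) and Ohler motif 5 (ratio 1.36, 0.079) did not pass in this smaller set of TSS-proximal summits, against ratios of 2.06 and 1.29 over flanks in the full list. In this comparison too the summit windows held more G and C, 42.2% against 40.3% at unbound promoters. The ratio of the CTCF core over flanks was 3.26 in the replicate 1 list alone. In the replicate 2 list alone Ohler motif 5 was 0.979 times as frequent at summits as in flanks (exact adjusted p = 0.94) and the homeodomain core did not pass (0.62). The initiator did not pass in either replicate's list (exact adjusted p = 0.055 and 0.063) or in wider windows (0.14).

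**Figure D4:**
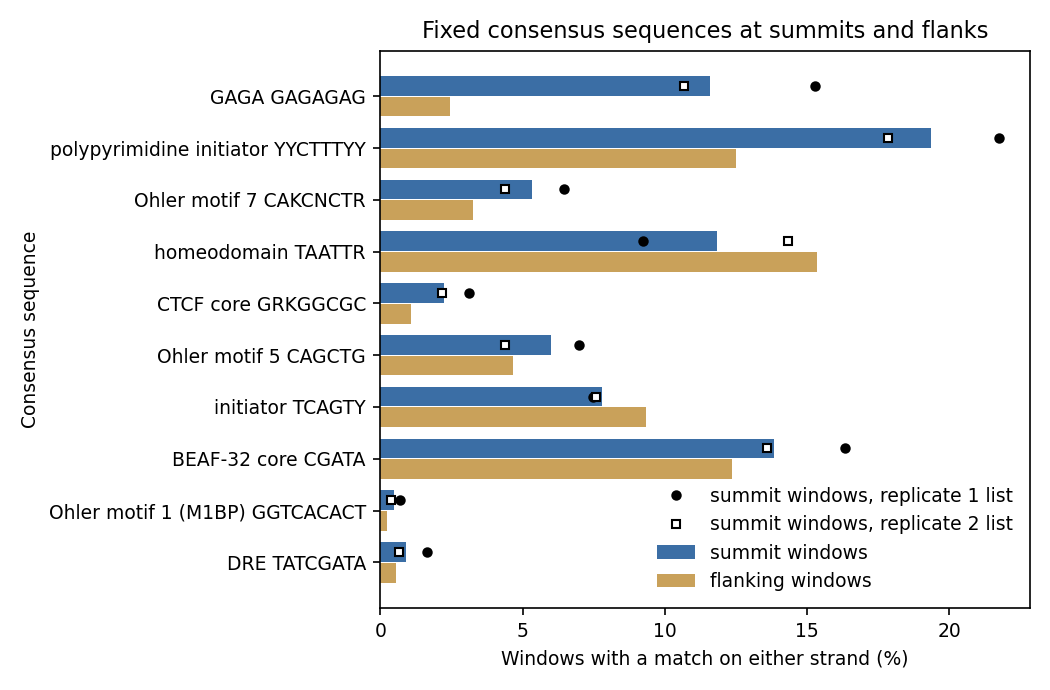
Percent of windows with a match on either strand (x axis) for the 10 consensus sequences with the smallest p (y axis). Blue bars are windows at the summits and brown bars flanking windows of the conservative list, with points and squares for summits of the replicate 1 and replicate 2 lists, and GAGA was found at 11.6% of summits and in 2.46% of flanks.

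Without a prior list of sequences, 446 of 32103 words of 8 bp were more frequent at summits than in flanks. The word GAGCGAGA led, at 11.3% of summits against 1.11% of flanks (Fisher's exact test, one-sided, adjusted p = 9.1e-97), followed by GAAAGAGA at 11.1% against 1.18% (exact adjusted p = 1.7e-92) and AGAGACGG at 5.29% against 0.1996% (exact adjusted p = 7.3e-58). The others among the first 10 were AAAGAGAC (5.79% of summits), AGAGCGAG (6.99%), GAGAGAGA (7.95%), AAGAGACG (4.09%), AGCGAGAC (4.72%), AGAGAGAG (7.19%) and GCTCGCAC (4.66%). With unbound promoters as control 168 words passed, and in the replicate 2 list alone 297.

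Strong peaks lay at promoters more often than weak ones. Of the 751 summits of highest signal 55.3% were TSS-proximal, and of the 751 of lowest signal 40.2% (odds ratio 1.84, 1.495 to 2.25, Fisher's exact test, p = 6.8e-09). In the replicate 1 list alone the odds ratio was 1.26 and Fisher's exact test was not passed (p = 0.076).

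Bound genes had a head-to-head neighbour more often than unbound genes. A head-to-head protein-coding start site within 1000 bp was present for 834 of 1525 bound genes, 54.7%, and for 33.9% of 12443 unbound genes (odds ratio 2.35, 2.11 to 2.62, Fisher's exact test, p = 5.1e-55). The share was 53.4% ± 0.519 (SD, n = 2) in the replicate lists. A summit between such a pair of start sites can count for both genes. With only the gene nearest to each summit counted, a setting chosen after the data had been seen, the shares were 43.2% of 1183 bound genes and 35.5% of the others (odds ratio 1.38, 1.22 to 1.56, Fisher's exact test, p = 2.1e-07).

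The gene of the tagged protein, CG10321 (FBgn0034643), lies at 2R 21634679 to 21638399 on the plus strand. In the conservative list 3 peaks overlapped it or the 2 kb to each side. A peak with signal 1100 had its summit 9 bp upstream of the TSS, another with signal 1164 lay 504 bp downstream of it, and a weak peak with signal 48.6 lay 3821 bp downstream. Peaks at the first 2 places were called in both replicates, with signals of 880 and 795 in replicate 1 and 270 and 462 in replicate 2.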

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

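Signal was found in 2 parts of the data that the comparisons of the report did not use, and the tests on both were chosen after the lists had been seen. The conservative list held 6 peaks on 6 unplaced sequences, with signals from 66.3 to 225 and a median of 77.3.

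The ranked list behind the conservative list held 126 peaks that scored at least 830 and were absent from the conservative list, with a median signal of 122 and a highest signal of 4055. Of these, 68 lay on 3R and 39 on 2L. Peaks at most 20 kb apart formed 24 groups of at least 2, which held 89 of the peaks, and 23 of the groups had no conservative peak between their ends. The strongest lay 657 bp upstream of Rh5, an opsin gene (signal 4055), 609 bp upstream of COX7AL2 (3178), 341 bp upstream of ssp3 (3174) and 89 bp upstream of eIF4A, a translation initiation factor gene (2439). The largest groups held 9 peaks at Rh5, 8 at InR, the insulin receptor gene, 7 at COX7AL2 and 7 at tara. Why these peaks were left out is not given in the sources used here. With the 124 on the main arms added back, the TSS-proximal share was 46.8% and 9 gene lists passed, the added list being that of the Polycomb and trithorax groups (Fisher's exact test, adjusted p = 0.025).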

How the results depend on the processing

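Of 509 values under alternative settings 468 kept their direction and side of the threshold or, for counts, stayed within 1.5 times. Chosen after the data had been seen were the settings with overlapping peaks reduced, peaks near CG10321 left out, passing peaks added back, mtd left out, and the nearest gene only for divergent promoters, whose odds ratio fell from 2.35 to 1.38. No paired analysis was possible because both samples belong to 1 group. The replicate overlap, the TSS-proximal share and the divergent promoters kept theirs in every setting run, 7 to 10 gene lists passed, against 8, and the 10 named words passed in each of 6 settings. The number of 8 bp words past the threshold ran from 297 to 490 without a replicate, against 446, and the cause was not tested. It was 168 against unbound promoters, where only TSS-proximal peaks enter, and 208 with words of 6 bp, of which fewer exist. The odds ratio of signal and TSS proximity ran from 1.26 to 1.64 without a replicate, and the lower value, without replicate 2, did not pass (Fisher's exact test, p = 0.076). The share of 2L was 0.918 of that expected by number of genes, since 2L holds more of the genes than of the length. Ohler motif 5 ran from 0.979 without replicate 1 to 1.52 without replicate 2, and the cause was not tested. Among single items, 7 gene list, 7 motif and 4 arm values newly passed, and 5, 7 and 3 no longer passed, as did 4 class values. The shares of promoters, other exons, introns and intergenic sequence could not change when coding sequence took precedence over UTRs. The 468 kept values therefore include some that were fixed in advance. Depth is unknown, and its effect was not tested.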

Other observations

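The tests on peaks at patterning genes were chosen before their odds ratio was known, and the other tests of this part, those on ribosomal protein genes and the CG10321 region included, after the results had been seen. Genes of further transcription factor families were examined with 3 lists, and these counts are not independent evidence. Of 85 homeobox genes 53 were bound, 62.4%, and of the 68 outside the patterning list 42 were bound (odds ratio 13.5, 95% interval 8.24 to 21.9, Fisher's exact test, adjusted p = 1.8e-23), among them otp, toy and ap. Of 33 T-box, Sox, Pax and forkhead genes 18 were bound, led by Sox21b (signal 3396), mid (2251) and SoxN (1861). Of 56 genes of Mediator, TFIID and RNA polymerase II subunits 10 were bound (odds ratio 1.78, 0.944 to 3.62, exact adjusted p = 0.13), led by Taf5 (204) and MED30 (136). By biotype, 13 of 290 tRNA genes were bound (4.48% against 9.57% of other genes, exact adjusted p = 0.0034) and 11 of 269 snoRNA genes (4.09% against 9.57%, exact adjusted p = 0.0033), while snRNA genes did not pass (exact adjusted p = 0.36).

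The leading words joined into longer ones, picked from the same windows in which they were counted. AAAGAGACGG was present at 3.53% of summits and 0.0499% of flanks, and 146 of its 788 places in the genome lay in a peak, 18.5%, where peaks cover 0.698% of the genome. AGAGCGAGAC was present at 1.90% of summits, and 67 of its 330 places lay in a peak. AGAGCGAGAC fell in 37 of the 751 windows of highest signal and in 2 of the 751 of lowest signal, and AAAGAGACGG in 35 and 12. GAGAGAG was found at 17.6% of the former and 6.66% of the latter (Fisher's exact test, adjusted p = 1.6e-09). Only 13 of 3006 summits lay in annotated transposable elements, 0.432% against 5.90% of relocated summits. Relocation used every base other than N, and whether reads could be placed uniquely in these elements was not examined. Of 85 peaks with a signal below the median of the ranked list, 17.4, 84 overlapped a stronger peak of the conservative list, against 1.92% of the others.

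Peaks at patterning genes may be due to recovery of highly transcribed promoters. The pooled odds ratio of the ribosomal protein, translation factor and proteasome lists was 3.72 (2.74 to 5.10). This lay below that of the patterning list (11.9, 6.26 to 22.2), the result set beforehand as counting against this explanation. However, the interval of the ribosomal protein list alone (7.51, 4.999 to 11.3) overlapped that of the patterning list, and the proteasome list had 0.354. Transcription was not measured but taken from list membership, so these values do not decide the question. The odds ratio adjusted for the number of start sites per gene was 11.9 (6.08 to 23.1), which argues against that number as the reason. DNA recovered without the tagged protein cannot be told apart from binding, because 0 control immunoprecipitations were among the samples. With 1 group no biological explanation was tested.

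Ribosomal protein promoters differed between the replicates. Of 93 genes 30 were bound in the replicate 1 list alone and 2 in the replicate 2 list alone (exact binomial test, adjusted p = 4.7e-06 over 19 lists), a test over genes, which are not replicates. A smaller number of promoter peaks in replicate 2 is argued against by the ratio of TSS-proximal peaks, 1.04 (0.953 to 1.13), beside that of bound ribosomal protein genes, 0.404 (0.237 to 0.689). Of the 30 genes, 27 (90%, 74.4 to 96.5) had a replicate 2 peak in the ranked list, as did 90% of the 300 other protein-coding genes bound in the replicate 1 list alone. Peaks of replicate 2 below the score threshold therefore cannot be told apart from other reasons for a difference in these genes. The reference used first, genes bound in neither list, had a share of 59.1%, below the interval of 74.4 to 96.5. It was replaced by the 300 genes after its values had been seen. No biological explanation was tested.

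Signal around CG10321 may reflect extra copies of the locus on the transgene, whose extent is not given in the sources used here. Among 11413 windows of 10 kb, the window that holds the gene lay at percentile 99.6 of the median signal of ranked peaks outside the conservative list. In the replicates it lay at 78.4 and 85.5, and the requirement that the replicates show it too was added after these percentiles had been seen, so the explanation cannot be told apart from binding at the locus. The strongest peak of the list, at Ip6k, lies within 10 kb of the gene, in a window at percentile 78.3 (99.97 in replicate 1 and 93.8 in replicate 2). The window 2R 21660001 to 21670000, which does not hold the gene, lay at 99.5 (96.6 in replicate 1 and 81.4 in replicate 2). The other windows between 2R 21580001 and 21700000 lay from 22.8 to 90.3. With the peaks near CG10321 left out, 8 gene lists passed, the number in the full list. No bound member of the lists lies near CG10321, so this setting could not change their counts and does not bear on the question.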
